A study of Ovis aries with 3 samples.

How the data were processed

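The data were UMI counts from 3 droplet-based single-cell RNA libraries of Hu sheep rumen epithelium at 42 days of age, 1 library each for milk only, milk plus alfalfa hay and milk plus concentrate starter. Groups were taken from the sample titles. Per the labels' protocols, the tissue was cut up and digested repeatedly in warm trypsin-EDTA, passed through a fine mesh and loaded on a droplet instrument. The deposited matrices held raw UMI counts per gene and barcode, made with Cell Ranger. The submitters' processing notes give version 3.1, whereas the deposited matrices carry version 5.0.0, per the file headers, and the sources used here do not settle which applies. Aligner settings, genome build, annotation release and the rule by which barcodes were selected are not given in the sources used here, so no coordinates are reported. The lowest UMI count of a barcode differed between libraries (727, 2263 and 1047 for milk only, hay and concentrate), so the barcode selection was not the same depth in each.

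The matrices listed 26247 genes by Ensembl identifier, of which 17043 had a symbol and 14653 a symbol carried by a single identifier. Symbols came from the deposited files. None of the identifiers matched the reference gene table (0 matches), so 9204 genes stayed unnamed. Counts of paralogues may be shared in ways the files do not show.

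Cells were kept with at least 500 genes and under 20% of UMIs from 13 mitochondrially encoded genes. These limits kept 54.8%, 73.7% and 53.1% of the milk-only, hay and concentrate barcodes. Under 500 genes were found in 38.0%, 5.97% and 29.9% of barcodes, and 29.6%, 26.0% and 43.3% were at or above the mitochondrial maximum. The doublet caller Scrublet (scanpy 1.11.5) marked 0 cells in each library, under the 0.5% set as the least for a working call, and was not used, so doublets were kept. Counts were scaled to 10000 UMIs per cell and log-transformed. From 2000 variable genes chosen within libraries, 30 principal components and 15 nearest neighbours were computed, and cells were clustered with Leiden (leidenalg 0.10.2) at a resolution of 0.6 without integration of libraries. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

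The 14 clusters were named from marker lists. A list needed at least 3 markers detected at 20 CPM and 3 markers at least 2-fold above the other cells, and the list with the highest median fold gave the name. This naming procedure, and the joining of spinous and granular markers into a differentiated keratinocyte-like class, were chosen after seeing the data. Cluster 8, the differentiated keratinocyte-like cluster, had KRTDAP among its 10 leading genes, and also S100A12, which is on the neutrophil list. Its median of 3268.5 UMIs was low for the milk-only library. Clusters with no winning list were counted as other keratinocytes, with KRT15, a basal keratin, at 2819 to 9806 CPM. The lower end does not by itself identify keratinocytes, since KRT15 stood at 2364 CPM in the fibroblast-like cluster and 1098 CPM in cluster 8. The lowest value was that of cluster 9, with 386 cells and medians of 673 genes and 0.45% mitochondrial UMIs. Cluster 9 is part of the keratinocyte shares and sums by this default only. Basal cells were not separated as a class, because KRT15 was abundant throughout. Levels within a class were therefore compared in cycling cells and in other keratinocytes. Medians in differentiated cells are also given, but hay had 42 and concentrate 38 such cells. A level near the 10 CPM limit was only a few UMIs in them, so calls in that class are uncertain. Most cycling cells lay in cluster 5 with hay and in cluster 7 with milk only and with concentrate, and the clusters holding most other keratinocytes differed between the libraries.

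Expression was the sum of UMIs over all keratinocytes of a library in CPM. With 1 library per diet there was no test. Levels carry exact Poisson, ratios exact conditional binomial and shares exact Clopper-Pearson intervals at 95%, and a count of 0 was given a limit of 3 counts. These cover counting error only. A gene was measured with at least 10 CPM in at least 1 library. For each of 29 gene lists the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 expression bins. Of these lists, 28 had measured genes. The list of sex-linked genes had 0 of 8 genes with a symbol and gave no result. The gene lists, cell markers, filters, most alternatives and the rule for named genes were set before the data were examined. Under that rule the text names, per comparison, the 8 genes with the highest and the 8 with the lowest ratio among genes with a symbol, at least 50 CPM in the higher library and at least a 2-fold difference whose interval excluded 1, leaving out ribosomal protein and mitochondrially encoded genes, and up to 4 genes from each list with the largest ratios. Genes named under it in 1 comparison are also given in others, and some genes it names are not reported here. The genes that name clusters lead them by rank, and the genes of the plot of gene levels, the cytokines IL17F and IL1B in immune cells, and the genes of the closing part on other observations were chosen after their values were seen.

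Code was tested on simulated counts for 3585 genes drawn from the libraries' means, with 200 genes changed, 50 at each of 1.5, 2, 4 and 8-fold. In each of the 3 comparisons 100% of the changed genes of each size were recovered in the right direction, and 0 of 3385 unchanged genes passed 1.5-fold. The intervals held the true ratio for 95.4% of genes for hay against milk only, 95.0% for concentrate against milk only and 95.3% for concentrate against hay. The rule named 16 of 16 genes changed by at least 4-fold. Of 100 unchanged lists, 2, 1 and 6 fell outside the central 95% of random lists in these comparisons. The simulated libraries shared a mean profile and differed by Poisson counting error only. These figures check the code and are not error rates for libraries of different animals.

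Alternatives set beforehand covered minimums of 200 and 1000 genes, a mitochondrial maximum of 10%, resolutions of 0.3 and 1.2, centring of log values per library, clustering without stage and cycle genes, thinning of cells, median-of-ratios scaling, totals without the 50 most abundant genes, per-cell means, minimums of 1 and 50 CPM, all kept cells, and classes weighted alike. Chosen after seeing the data were the depth of 2000 UMIs for thinning, which left out 233, 0 and 127 cells with milk only, hay and concentrate, a common minimum of 2263 UMIs, a minimum at 38.4% of each library's median keratinocyte UMI count, both of these also with the classes of the main clustering kept, no mitochondrial maximum, a Scrublet score limit of 0.2, and sums without cluster 6 or the differentiated cluster. The expression of shares as ratios between libraries, and the choice of the basal, spinous, cornified, butyrate, S phase and G2 and M phase lists as main results, were also made after seeing the data.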

Results

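Droplet-based single-cell RNA sequencing was carried out on rumen epithelium from Hu sheep lambs at 42 days of age. The lambs had received milk only, milk plus alfalfa hay, or milk plus a concentrate starter, and each diet was represented by 1 library. The milk-only, hay and concentrate libraries held 63057979, 56861548 and 60220174 UMIs in 7032, 9543 and 9214 barcodes. After filtering, 3850, 7031 and 4891 cells remained, with medians of 11021, 5887 and 8050 UMIs and 1746, 1128 and 1464 genes per cell. Because no diet had a replicate library, no difference had a replicate check and no test between diets was made. A difference between diets cannot be told apart from a difference between the animals sampled or between library preparations. The 95% intervals given with shares (exact Clopper-Pearson), expression levels (exact Poisson) and ratios (exact conditional binomial) cover counting error only.

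Most cells were keratinocytes, the cells that build the stratified rumen lining: 88.4% of the milk-only cells, 99.4% of the hay cells and 95.6% of the concentrate cells. Cells resembling differentiated keratinocytes, which leave the basal layer and form the horny surface, made up 19.0% (17.8 to 20.3) of the milk-only library, 0.597% (0.431 to 0.807) of the hay library and 0.777% (0.550 to 1.06) of the concentrate library. Their share was 31.8 times higher with milk only than with hay (23.3 to 44.5) and 24.5 times higher than with concentrate (17.7 to 34.9). Cycling-like cells, marked by TOP2A and CENPF, made up 9.12% (8.23 to 10.1), 16.1% (15.3 to 17.0) and 14.2% (13.2 to 15.2) of the 3 libraries. The cycling share was 1.77 times higher with hay (1.57 to 2.0) and 1.55 times higher with concentrate (1.37 to 1.77) than with milk only. These shares count unlike clusters: hay had 1129 cells in cycling cluster 5, milk only and concentrate 335 and 628 in cycling cluster 7. G2 and M phase transcripts summed over keratinocytes were not higher with hay than with milk only (median log2 ratio -0.33). Of 27 such genes 5 were lower by at least 1.5-fold and 0 higher. The S phase median was 0.16, with 0 of 16 genes past 1.5-fold. A single cluster led by A2ML1, KRT36 and S100A9 formed the differentiated keratinocyte-like class, and 90.1% of its cells came from the milk-only library, so it may be a state of that library rather than a cell type. The same holds for 6 of the 7 keratinocyte clusters outside the cycling and differentiated classes, which drew from 89% to 99.7% of their cells from 1 library. Clustering without the keratinocyte stage and cycle genes gave differentiated shares of 19.1%, 0.597% and 0.777%, but other settings moved them: 19.6%, 4.31% and 2.84% at resolution 0.3, 19.0%, 0.541% and 5.56% at resolution 1.2, and 5.12%, 1.18% and 2.26% with at least 1000 genes per cell. The closing part on processing gives the ratios under each alternative that moved them.

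Immune cells were most frequent with milk only. T or NK-like cells, led by IL17F and PTPRC, made up 8.60% (7.73 to 9.53) of the milk-only library, 0.114% (0.0491 to 0.224) of the hay library and 0.90% (0.654 to 1.21) of the concentrate library. Macrophage or dendritic-like cells, led by IL1B and C1QA, made up 2.91% (2.40 to 3.49), 0.441% (0.30 to 0.625) and 1.02% (0.760 to 1.35). Fibroblast-like cells, led by COL3A1, were seen mainly in the concentrate library at 1.21% (0.920 to 1.55), with 1 cell in the hay library. The milk-only library had 0 of 3850 cells, with an upper bound of 0.0958%. Endothelial-like cells were also seen mainly in the concentrate library, at 1.31% (1.01 to 1.67), with 3 cells in the milk-only library. The hay library had 0 of 7031 cells, with an upper bound of 0.0525%. The shallowest deposited barcode had 727 UMIs in the milk-only, 2263 in the hay and 1047 in the concentrate library, and differentiated keratinocyte-like cells had a median of 3268.5 UMIs. Among cells with at least 2263 UMIs the ratio of differentiated shares was 23.7 over hay (17.3 to 33.3) and 21.5 over concentrate (15 to 32.0) with the same classes, and 5.11 (3.97 to 6.63) and 3.24 (2.52 to 4.18) when these cells were clustered anew. With the same classes and this minimum, T or NK-like cells made up 8.85%, 0.114% and 0.425% of the milk-only, hay and concentrate libraries, and fibroblast-like and endothelial-like cells 0.870% and 0.743% of the concentrate library. With the minimum at the same share of each library's median UMI count, T or NK-like cells made up 6.35%, 0.114% and 0.177%, and fibroblast-like and endothelial-like cells 0.488% and 0.377% of the concentrate library.

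**Figure D1:**
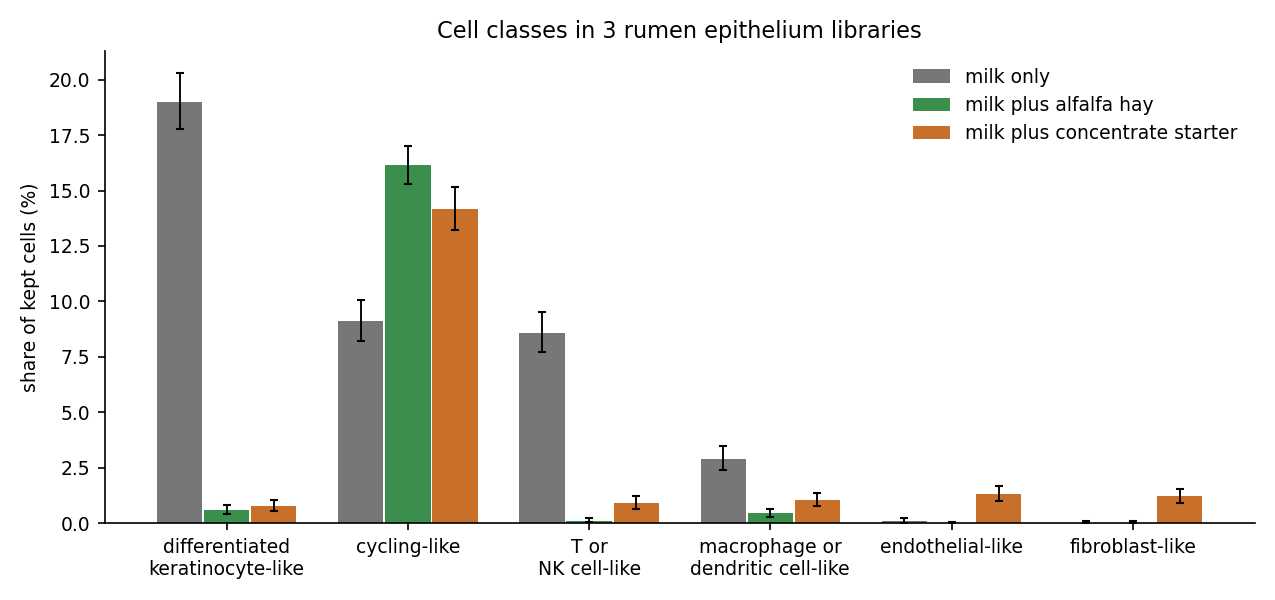
Share of kept cells, in percent, for 6 classes of cells in the milk-only, hay and concentrate libraries; bars show the share and lines its 95% exact interval, which covers counting error only. Differentiated keratinocyte-like cells made up 19.0%, 0.597% and 0.777%, and T or NK-like cells 8.60%, 0.114% and 0.90%.

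UMIs were summed over all keratinocytes of a library, 46992246 with milk only, 45045382 with hay and 44433705 with concentrate, and a gene's share of that sum is given in CPM. The median log2 ratio of 3953 measured genes was -0.16 for hay against milk only, 0.06 for concentrate against milk only and 0.20 for concentrate against hay. Median-of-ratios scaling moved these to 0.13, 0.10 and -0.05. Each gene list was therefore compared with 10000 random lists of the same size and expression in the same comparison, as a description of these libraries, and is called higher or lower where its median fell outside the central 95% of them. Some lists were measured only in small part, among them 6 of 38 cornified, 6 of 19 spinous, 9 of 38 inflammatory and 4 of 25 antimicrobial genes. Only 4 of 21 retinoid and vitamin D genes and 3 of 17 antigen presentation genes were measured. Their medians describe those genes and not the whole list.

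The comparison of hay with milk only asked how keratinocytes differed when a forage was offered beside milk. Genes of the cornifying surface were lower with hay. TGM1 (ENSOARG00000019146), the transglutaminase that cross-links the cornified envelope, stood at 59.9 CPM (57.7 to 62.1) with milk only and 4.48 CPM (3.89 to 5.15) with hay, a 13.4-fold lower level (11.6 to 15.5). SPINK5, an inhibitor of epidermal proteases, was 6.89-fold lower (6.68 to 7.11), and KRTDAP, a protein of differentiating keratinocytes, 8.83-fold lower (8.39 to 9.29).

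Lists of the upper layers and of differentiation regulators were lower in this comparison. Of 6 measured genes of the cornified envelope and granular layer, 4 were lower by at least 1.5-fold and 0 higher (median log2 ratio -2.25). CNFN, a cornified envelope protein, stood at 72.6 CPM with milk only and at 1 UMI over all hay keratinocytes, a ratio of 0.000306 with an upper bound of 0.00171. Of 6 spinous layer genes, 3 were lower and 0 higher (median -1.14), among them the desmosomal cadherin DSC2 at 3.41-fold (3.23 to 3.61). Of 9 differentiation regulators, 7 were lower (median -1.13), including the transcription factors KLF4, 4.32-fold (4.03 to 4.63), and BHLHE40, 9.41-fold (8.88 to 9.98). Genes of the basal layer had a median of -0.29, within the range of random lists, and of -0.46, below it, without the differentiated cluster. CNFN and KRTDAP are among the leading genes of the differentiated cluster. Without that cluster the cornified median was -0.84, and with the keratinocyte classes weighted alike -0.59, both within the range of random lists. The spinous median came within that range with the classes weighted alike (-0.42) and in cycling cells (-0.61), but lay below it without the differentiated cluster (-0.75) and in cells outside the cycling and differentiated clusters (-0.79). Regulators lay below the range in those other keratinocytes (-1.13), in cycling cells (-1.01) and in differentiated cells (-0.63, with 42 such cells in the hay library).

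Of 13 genes of butyrate oxidation and ketogenesis, 5 were higher with hay and 1 lower (median 0.37). HADH, which oxidises hydroxyacyl-CoA, was 2.78-fold higher (2.58 to 2.99), and BDH1, which interconverts ketone bodies, stood at 870 against 461 CPM, 1.89-fold higher (1.86 to 1.92). The same median was 0.50 in cells outside the cycling and differentiated clusters and 0.50 in cycling cells, both above the random range, and 0.33 in differentiated cells, within it. Within the 12 measured genes of short-chain fatty acid, ion and urea transport, 3 were higher and 3 lower (median 0.21, above the random range). The urea transporter SLC14A1 was 17.6-fold higher (12.4 to 25.6), while the sodium pump subunit ATP1B1 was 5.04-fold lower (4.87 to 5.22). The butyrate median was 0.019 with genes counted from 1 CPM and 0.03 without cluster 6, which drew 1021 of its 1024 cells from the milk-only library and was led by ZFP36 and ATF3, and the transport median 0.08 with the 50 most abundant genes out of the totals, all within the random range. Heat shock genes were higher (median 0.43, 3 of 10 higher and 1 lower), with HSPH1 2.10-fold higher (2.02 to 2.20). The nuclear genes of oxidative phosphorylation had a slightly lower median of -0.21 over 43 genes, which turned to 0.09 under median-of-ratios scaling while staying below the random range.

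The immune cell share was 0.555% with hay against 11.5% with milk only, and several immune and stress lists were lower in hay keratinocytes. Of 9 inflammatory signalling genes all 9 were lower (median -3.88), and of 17 immediate early genes 16 were lower (median -2.07). S100A8, a calcium-binding alarmin, was 49.4-fold lower (46.9 to 52.2), its partner S100A9 47.1-fold (44.5 to 50.0), and ZFP36, which destabilises cytokine mRNAs, 13.0-fold (12.7 to 13.4). The interferon response (6 of 9 lower, median -1.74), antimicrobial defence (4 of 4, -5.59), hypoxia targets (4 of 7, -1.07), apoptosis and p53 targets (8 of 9, -1.08), oxidative stress defence (6 of 17, -0.49), the unfolded protein response (9 of 20, -0.45), growth factor signalling (17 of 22, -0.95) and the desmosome (5 of 11, -0.51) were also lower. Among them, the cell cycle inhibitor CDKN1A was 10.8-fold lower (9.77 to 11.9) and the glutathione transferase GSTA1 31.4-fold lower (29.8 to 33.0). S100A8 and S100A9 belonged to both the inflammatory and the antimicrobial list. The unfolded protein response turned to 0.73, above the random range, in differentiated cells, and the desmosome list lay within the range in other keratinocytes (-0.37), cycling cells (-0.47) and differentiated cells (0.04).

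Among single genes with the largest ratios, the gluconeogenic enzymes FBP1 (3.62-fold, 3.40 to 3.87) and FBP2 (2.81-fold), the heat shock gene HSPA6 (3.40-fold), the lipopolysaccharide co-receptor LY96 (3.37-fold), the monoamine oxidase MAOA (3.08-fold), AHCYL2 (3.08-fold) and the thioesterase ACOT8 (2.92-fold) were higher with hay. The lowest included the elastase inhibitor PI3, with 1 UMI against 68.8 CPM (ratio 0.000323, upper bound 0.00180), the flavin monooxygenase FMO2 (196-fold, 119 to 350), the proteoglycan DCN (57.5-fold, 48.4 to 68.9) and S100A12 (51.4-fold, 48.3 to 54.8). For proliferation, the S phase median was 0.16, just above the random range, with 0 of 16 genes past 1.5-fold (0.01, within that range, without the differentiated cluster, and within it in each class), and the G2 and M phase median was -0.33, within it, with 5 of 27 lower. Within cycling cells the G2 and M phase median was -0.70, below the random range, with 22 of 34 genes lower and 0 higher. Over keratinocytes it also fell below that range with the classes weighted alike (-0.65), without cluster 6 (-0.75), without the differentiated cluster (-0.52) and without both (-1.02). The remaining lists lay within the random range: tight and gap junctions (-0.45), PPAR targets (-0.44), cholesterol synthesis (0.17), mitochondrially encoded genes (0.01), glycolysis (-0.40), antigen presentation (-0.68), histone acetylation (-0.18), and retinoid and vitamin D genes (0.00).

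Calls also differed between all keratinocytes and single classes. In cells outside the cycling and differentiated clusters, cholesterol synthesis was above the random range for hay against milk only (0.57), and the cornified list (-0.78) and oxidative phosphorylation (-0.08) lay within it. In cycling cells antigen presentation was below it (-1.01), and the cornified list (-1.09) and hypoxia targets (-0.69) were within it. In differentiated cells glycolysis was below it (-0.93), and the cornified (-0.31), spinous (-0.24), transport (0.23), interferon (-0.26), apoptosis and p53 (-0.48) and growth factor (-0.06) lists were within it. Of 95 named gene ratios in this comparison, 13 moved by more than 1.5-fold without the differentiated cluster, among them the log2 ratios of TGM1 from -3.74 to -2.50, KRTDAP from -3.14 to -1.70, CNFN from -11.67 to -5.76, PI3 from -11.60 to -7.24, DSC2 from -1.77 to -0.90, S100A8 from -5.63 to -4.52, S100A9 from -5.56 to -4.49 and S100A12 from -5.69 to -4.43. No hay count of CNFN was left without the differentiated cluster, so its -5.76 rests on the limit of 3 counts and is not a measured ratio. Without cluster 6, 16 ratios moved, among them ZFP36 from -3.70 to -1.53, BHLHE40 from -3.23 to -1.34, KLF4 from -2.11 to -1.10, CDKN1A from -3.43 to -2.67 and HSPA6 from 1.76 to 3.14. Without it the immediate early median was -0.67 and the inflammatory median -1.85, both still below the random range, and the unfolded protein median -0.37, within it.

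**Figure D2:**
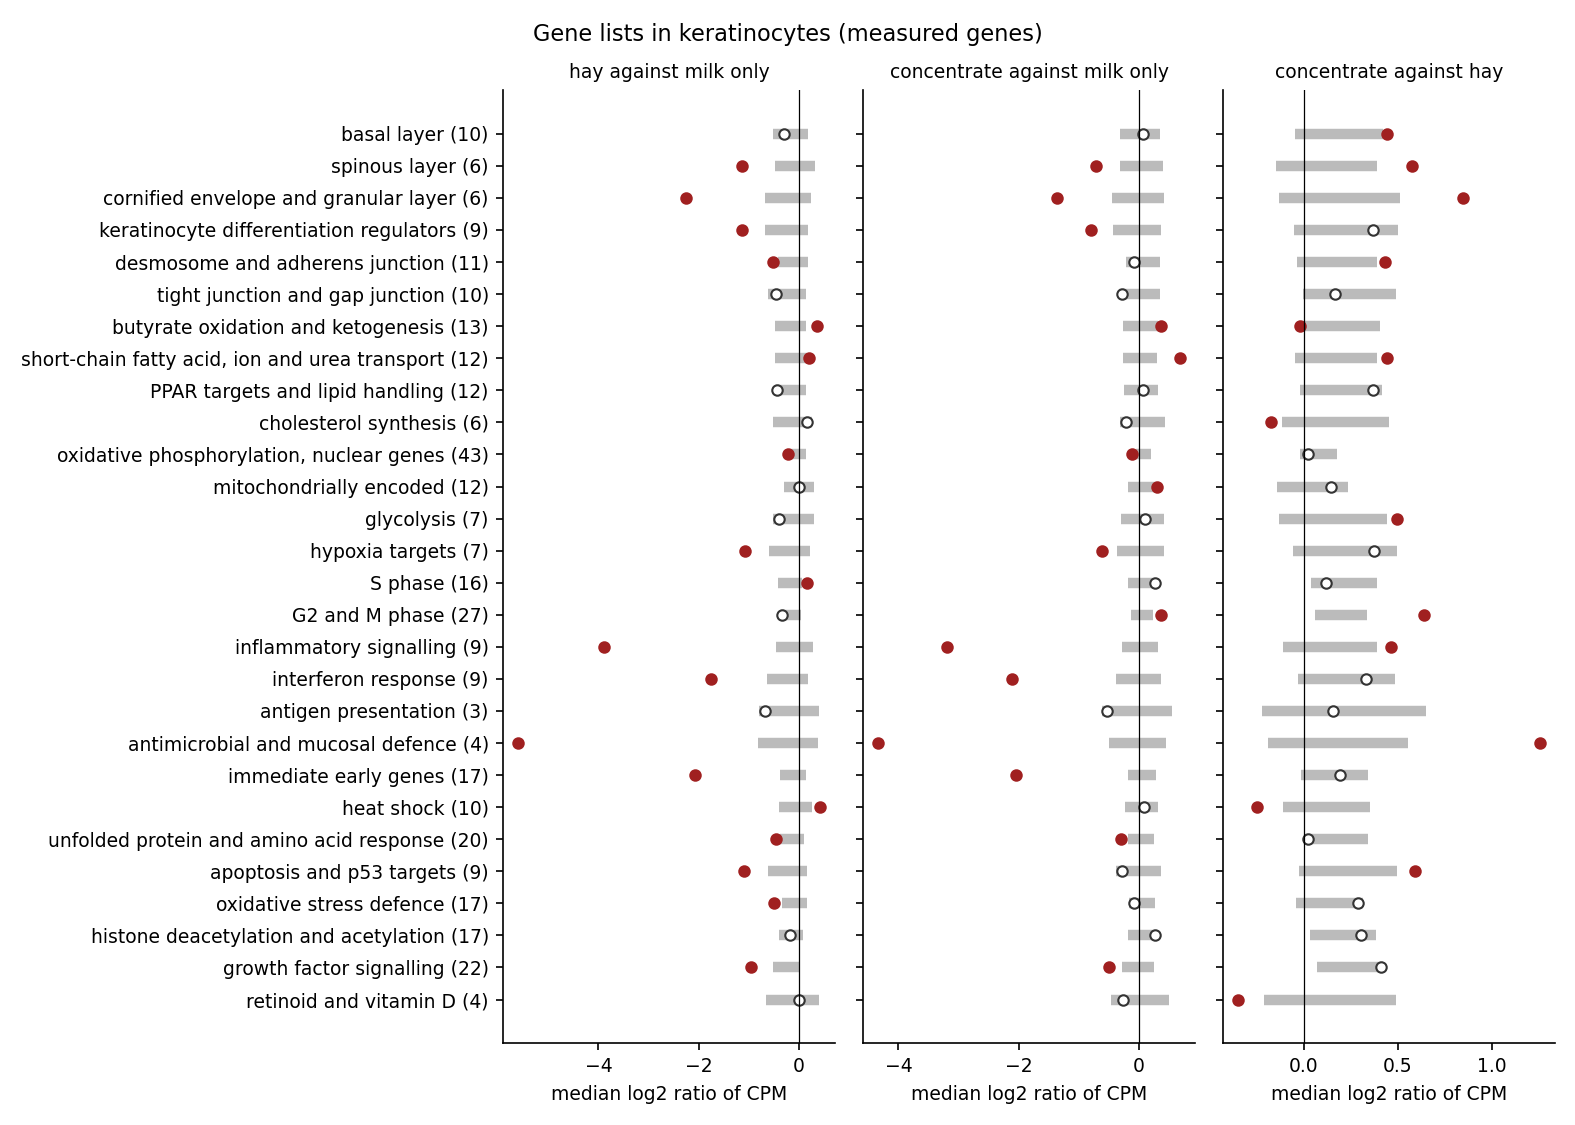
Median log2 ratio of CPM in keratinocytes for 28 gene lists (number of measured genes in parentheses), with 1 panel per comparison and a separate horizontal scale in each. Dots are list medians, grey bars the central 95% of 10000 random lists of the same size and expression, and filled red dots lie outside the bar. Inflammatory signalling stood at -3.88, -3.20 and 0.46.

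The comparison of concentrate with milk only bears on the question of the study, whether an early starter feed alters keratinocyte maturation and how ruminal butyrate is involved. Cornification genes were lower with concentrate too. TGM1 was 7.49-fold lower (6.71 to 8.39), SPINK5 3.65-fold (3.57 to 3.74) and KRTDAP 5.90-fold (5.65 to 6.16) lower than with milk only. The fatty acid-binding protein FABP4 (ENSOARG00000009344), a carrier for lipids, reached 5464 CPM with concentrate against 1769 CPM with milk only, 3.09-fold higher (3.06 to 3.11).

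The cornified envelope and granular list had a median of -1.36 (4 of 6 lower), the spinous list -0.72 (3 of 6 lower) and the regulators -0.79 (6 of 9 lower). CNFN was 293-fold lower (164 to 588), and KLF4 3.89-fold lower (3.64 to 4.17). The basal list lay at 0.06, within the random range. Desmosome genes as a list did too, at -0.09, although the desmosomal plaque protein DSP was 2.56-fold higher (2.5 to 2.62) and DSC2 2.29-fold lower (2.18 to 2.40). The cornified median was -0.04 without the differentiated cluster and -0.02 with the classes weighted alike, and the spinous median -0.18 with the classes weighted alike, all within the random range. In other keratinocytes the spinous median was -0.30, within the range, and in cycling cells -0.43, below it, and the regulators lay below it in both, at -0.69 and -0.48. In differentiated cells, of which the concentrate library had 38, the cornified median turned to 0.59, above the range, while the regulators (-0.48) and the spinous list (0.16) lay within it. The log2 ratio of LYPD3, a surface protein that was 1.80-fold lower over all keratinocytes (1.75 to 1.86), turned to 0.06 with that weighting.

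Genes of butyrate oxidation and ketogenesis were higher in the concentrate library as well (5 of 13 higher, 0 lower, median 0.36), with HADH at 2.07-fold (1.91 to 2.23). Their median was 0.41 in other keratinocytes and 0.36 in cycling cells, both above the random range, and 0.14 in differentiated cells, within it, with 5 of 14 genes lower and 1 higher. Transport genes were higher (8 of 12 higher, 2 lower, median 0.68). SLC14A1 was 10.3-fold higher (7.22 to 15.1), the carbonic anhydrases CA12 3.0-fold (2.94 to 3.06) and CA1 1.54-fold higher, and ATP1B1 was 3.55-fold lower (3.44 to 3.66). The butyrate median was 0.22 with genes counted from 1 CPM, 0.23 without cluster 6 and 0.32 as a mean of per-cell proportions, and the transport median 0.20 with the 50 most abundant genes out of the totals, all within the random range. The 12 mitochondrially encoded genes had a median of 0.30, above the random range (0.24, within it, in other keratinocytes), beside a median mitochondrial share of 10.2% in kept concentrate cells against 6.18% with milk only, and the nuclear genes of oxidative phosphorylation one of -0.12, below it.

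The immune cell share was 1.92% with concentrate against 11.5% with milk only. Inflammatory signalling (8 of 9 lower, median -3.20), immediate early genes (15 of 17, -2.05), the interferon response (7 of 9, -2.12), antimicrobial defence (4 of 4, -4.34), hypoxia targets (4 of 7, -0.61), the unfolded protein response (6 of 20, -0.31) and growth factor signalling (9 of 22, with 1 higher, -0.50) lay below the random range. In differentiated cells hypoxia targets turned to 0.92, above the range, and the inflammatory (-0.36), immediate early (-0.26), unfolded protein (0.24) and growth factor (0.00) lists lay within it. S100A9 was 27.0-fold lower (25.8 to 28.3), ZFP36 9.85-fold (9.63 to 10.1), the ubiquitin-editing enzyme TNFAIP3 15.6-fold (13.3 to 18.3) and ISG15, an interferon-induced modifier, 12.2-fold (10.3 to 14.5). The immunoproteasome subunits PSMB8 (4.64-fold, 4.29 to 5.02) and PSMB9 (4.70-fold, 4.28 to 5.18) and the class I light chain B2M (5.78-fold, 5.05 to 6.63) were lower with concentrate.

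Genes with the largest increases over milk only were PTHLH, encoding parathyroid hormone-related protein (22.4-fold, 19.2 to 26.2), the galectin LGALS1 (20.2-fold, 18.6 to 21.9), the serine synthesis enzyme PSPH (3.66-fold), MACC1 (3.51-fold), RNASEH2C (3.42-fold), the thioesterase THEM5 (3.39-fold) and LY96 (3.20-fold). Beside CNFN, S100A9 and TNFAIP3, the largest decreases were in PI3 (78.4-fold, 57.2 to 110), FMO2 (46.0-fold, 35.9 to 60.0), the cornified envelope gene PRD-SPRRII (19.8-fold, 17.1 to 23.1), RND1 (16.5-fold, 14.0 to 19.6) and RCAN1 (15.5-fold, 13.7 to 17.7). G2 and M phase genes were higher (5 of 27 higher, 1 lower, median 0.36), with the centromere protein CENPF at 1.98-fold (1.92 to 2.05), and the S phase median was 0.27, within the random range. The G2 and M phase median depended on the cells included: it was 0.07 within cycling cells, 0.18 in other keratinocytes and -0.08 without cluster 6, all within the random range, and -0.34, below the random range, without cluster 6 and the differentiated cluster. Within the random range were tight and gap junctions (-0.29), PPAR targets (0.06), cholesterol synthesis (-0.21), glycolysis (0.09), antigen presentation (-0.54), heat shock (0.08), apoptosis and p53 targets (-0.28), oxidative stress defence (-0.08), histone acetylation (0.26), and retinoid and vitamin D genes (-0.26).

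In single classes, antigen presentation, with 3 of 17 genes measured, was below the random range for concentrate against milk only, although not over all keratinocytes. Its medians were -0.64 in other keratinocytes, -1.0 in cycling cells and -1.31 in differentiated cells. In each class 2 of the 3 genes were lower by at least 1.5-fold, and over all keratinocytes 1, B2M. Apoptosis and p53 targets were below the random range in other keratinocytes (-0.43), where the cornified list lay within it (-0.01). The cornified (-0.52) and unfolded protein (-0.19) lists were within it in cycling cells. In differentiated cells the basal (-1.46) and cholesterol (-0.56) lists were below it, the desmosome list above it (0.67), and transport (0.03) and G2 and M phase (0.19) within it. Of 90 named gene ratios, 13 moved by more than 1.5-fold without the differentiated cluster, among them the log2 ratios of TGM1 from -2.91 to -1.64, KRTDAP from -2.56 to -1.69, CNFN from -8.20 to -7.31, PI3 from -6.29 to -3.75, PRD-SPRRII from -4.31 to -1.24, S100A9 from -4.76 to -3.23 and DSC2 from -1.20 to -0.36. Without cluster 6, 20 moved, among them ZFP36 from -3.30 to -1.14, TNFAIP3 from -3.96 to -1.93, RND1 from -4.04 to -1.53, RCAN1 from -3.96 to -1.69 and KLF4 from -1.96 to -0.95. Without it the immediate early median was -0.39 and the inflammatory median -1.93, both still below the random range, and the hypoxia median -0.21, within it.

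The comparison of concentrate with hay asked how the solid feeds differed from each other. LGALS1 (ENSOARG00000013956), a galectin that binds cell-surface glycans, stood at 269 CPM with concentrate and 1.62 CPM with hay, 166-fold higher (132 to 212). FABP4 was 8.49-fold higher with concentrate (8.39 to 8.60), THEM5 11.3-fold (10.8 to 11.9) and PTHLH 4.93-fold (4.56 to 5.35). PSMB9 was 6.97-fold lower (6.36 to 7.66), PSMB8 5.49-fold lower (5.08 to 5.95), and B2M 5.28-fold lower (4.61 to 6.06). BDH1 was 1.61-fold lower with concentrate than with hay (1.58 to 1.64).

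The ratio of differentiated keratinocyte-like shares, concentrate over hay, was 1.30, with an interval of 0.816 to 2.07 that included 1. It depended on the setting: 0.659 (0.536 to 0.809) at resolution 0.3, 10.3 (7.31 to 14.9) at resolution 1.2, 1.92 (1.36 to 2.73) with at least 1000 genes, 1.84 (1.46 to 2.32) in thinned cells and 2.07 (1.34 to 3.20) above the same share of each library's median UMI count. The cycling share was 1.14 times higher with hay (1.04 to 1.25), a difference that turned to 0.97 among cells above the same share of each library's median UMI count. Its interval also reached 1 with a mitochondrial maximum of 10% (1.05), without one (1.05), at resolutions 0.3 (1.06) and 1.2 (1.06), with centred values, without stage and cycle genes (1.03), in thinned cells (1.06), with the common UMI minimum (1.04) and with the relative minimum and the classes kept (1.06). Cycling cells fell mostly into cluster 5 with hay and cluster 7 with concentrate. In keratinocytes, 4 of 6 cornified genes were higher with concentrate (median 0.85), as were 2 of 6 spinous genes (0.58) and 2 of 10 basal genes (0.44), including the hemidesmosomal collagen COL17A1 at 1.59-fold (1.52 to 1.66). SPINK5 was 1.89-fold higher (1.82 to 1.96) and TGM1 1.78-fold higher (1.5 to 2.13). The spinous and cornified medians came within the random range when cells were thinned to 2000 UMIs, at 0.18 and 0.26, and without the differentiated cluster, at 0.31 and 0.54. Within classes, the cornified median lay within the range in all 3, and the basal median turned to -0.99, below the range, in differentiated cells. That class held only 38 concentrate and 42 hay cells, so its calls between these diets rest on few UMIs per gene.

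Division genes were higher with concentrate than with hay: 15 of 27 G2 and M phase genes were higher by at least 1.5-fold and 0 lower (median 0.64), among them the spindle protein NUSAP1 at 1.86-fold (1.76 to 1.97) and the mitotic regulator CDC20 at 1.80-fold (1.60 to 2.04). The median was 0.70 in cycling cells, and 0.18 in other keratinocytes and -0.19 in differentiated cells, both within the random range. The butyrate and ketogenesis median of -0.02 lay just below the random range, and 0.05, within it, over all kept cells. Other lists above the random range were transport (4 of 12 higher, 2 lower, median 0.44), glycolysis (3 of 7, 0.50), desmosome (3 of 11, 0.43), inflammatory signalling (4 of 9 higher, 1 lower, 0.46), antimicrobial defence (3 of 4, 1.25) and apoptosis and p53 targets (6 of 9, 0.59). PKM, the last enzyme of glycolysis, was 2.08-fold higher (2.03 to 2.14), DSP 1.86-fold (1.82 to 1.89), and S100A8 3.26-fold (3.07 to 3.47). CA1 was 1.87-fold higher (1.86 to 1.87) and CA2 4.60-fold lower (3.96 to 5.38). In differentiated cells the transport median turned to -0.46, below the range, and it was 0.37, within it, in cycling cells. The transport median was 0.24 and the inflammatory median 0.30, both within the random range, when the 50 most abundant genes were taken out of the totals.

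Lists below the random range were heat shock (median -0.25, with HSPH1 2.16-fold lower, 2.07 to 2.26), cholesterol synthesis (-0.17) and retinoid and vitamin D genes (-0.35). In the cholesterol list IDI1, an isomerase of isoprenoid synthesis, was 3.38-fold lower (3.23 to 3.53) and was the only one of 6 genes past 1.5-fold. Of 4 measured genes of the retinoid list, 2 were lower by at least 1.5-fold and 1 was higher. The retinoic acid-degrading enzyme CYP26A1 was 2.40-fold lower (2.29 to 2.5) and the retinal dehydrogenase ALDH1A1 2.12-fold lower (2.08 to 2.17). RARG was higher, with a log2 ratio of 0.76. AOX1 (2.57-fold, 2.43 to 2.71) and FBP1 (2.19-fold, 2.08 to 2.32) were also lower, while GSTA1 (5.60-fold, 5.31 to 5.91), IGFBP5 (5.48-fold, 5.24 to 5.73), S100A12 (4.07-fold, 3.80 to 4.37) and SESN3 (4.0-fold, 3.65 to 4.39) were higher. Within the random range were the regulators (0.37), tight and gap junctions (0.17), PPAR targets (0.37), oxidative phosphorylation (0.02), mitochondrially encoded genes (0.14), hypoxia targets (0.37), S phase (0.12), the interferon response (0.33), antigen presentation (0.16), immediate early genes (0.19), the unfolded protein response (0.02), oxidative stress defence (0.29), histone acetylation (0.31) and growth factor signalling (0.41).

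In single classes, growth factor signalling was above the random range for concentrate against hay in other keratinocytes (0.54), cycling cells (0.61) and differentiated cells (0.89), although not over all keratinocytes. In other keratinocytes the spinous (0.34), butyrate (0.09) and G2 and M phase (0.18) lists lay within it. In cycling cells immediate early genes were below it (-0.10), and the basal (0.34), spinous (0.32), desmosome (0.36), cholesterol (0.05) and inflammatory (0.42) lists were within it. In differentiated cells hypoxia targets (1.44), immediate early genes (1.17) and oxidative stress defence (0.57) were above it, the unfolded protein response (-0.44) was below it, and G2 and M phase (-0.19), cholesterol synthesis (-0.11), antimicrobial defence (0.30), heat shock (-0.29), apoptosis and p53 targets (0.35) and retinoid genes (-0.42) were within it. The butyrate median there was -0.72, below the range. Of 80 named gene ratios, 3 moved by more than 1.5-fold without the differentiated cluster and 0 without cluster 6. The log2 ratio of CNFN went from 3.48 to -1.56, of PI3 from 5.31 to 3.49 and of IL36A from 1.48 to 0.59. No hay count of CNFN was left without that cluster, so its -1.56 rests on the limit of 3 counts. It does not show a lower level with concentrate.

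Of the genes whose identifiers carried no symbol, ENSOARG00000000165 and ENSOARG00000009066 were higher in both fed libraries, with log2 ratios against milk only of 4.82 and 3.94 for hay and 4.28 and 3.36 for concentrate. ENSOARG00000025555 and ENSOARG00000020393 were lower, at -5.02 and -3.33 for hay and -5.87 and -4.39 for concentrate. They were chosen after their values were seen. Genes without a symbol took 41.3%, 39.6% and 37.6% of keratinocyte UMIs in the milk-only, hay and concentrate libraries.

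**Figure D3:**
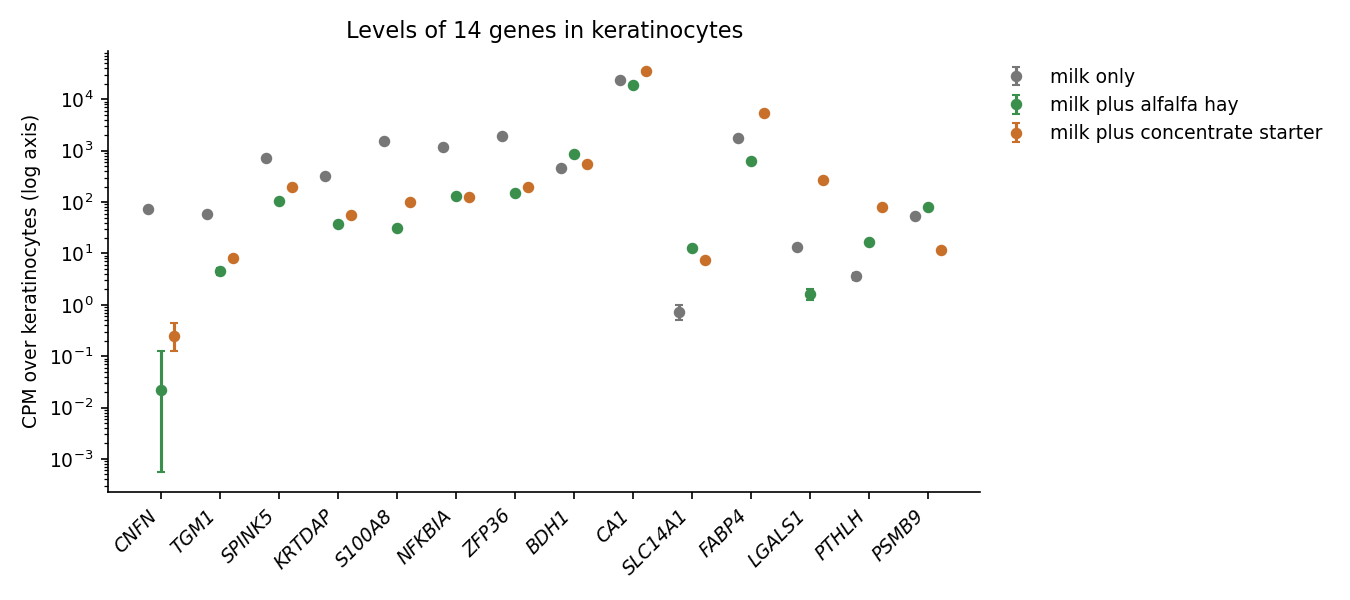
Level in keratinocytes, in CPM on a log axis, of 14 genes in the 3 libraries; points are sums over all keratinocytes of 1 library and lines their 95% exact Poisson intervals, mostly smaller than the points. The genes were chosen after their values were seen. TGM1 stood at 59.9, 4.48 and 7.99 CPM and LGALS1 at 13.3, 1.62 and 269 CPM.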

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

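The tests below were chosen after the results were seen, except that of a handling response in immune cells, whose bounds were set beforehand.

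Barcodes below 500 genes and with a mitochondrial share under 20% were outside the reported comparisons, although most entered the alternative with a minimum of 200 genes, and they held cornified transcripts above the limit that a count of 0 allows. The 6 measured genes of the cornified list summed to 2584 CPM in 1101 such barcodes with milk only, 89.6 CPM in 34 with hay and 263 CPM in 337 with concentrate. In kept keratinocytes the same sums were 1106, 198 and 360 CPM. KRT15 stood at 2396, 2104 and 3016 CPM in the left-out barcodes. No explanation was tested.

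The first pattern was the larger share of differentiated keratinocyte-like cells in the milk-only library, at 19.0% against 0.597% and 0.777%. Different lowest UMI counts as the whole cause are argued against, because with a common minimum the ratio of shares was 5.11 over hay (3.97 to 6.63) and 3.24 over concentrate (2.52 to 4.18), and with a minimum at the same share of each median it was 19.1 and 9.23. Both settings also redrew the clusters, and with the classes kept the common minimum gave 23.7 and 21.5 and the relative minimum 14.7 and 13.6. Removal of such cells from the fed libraries by the filters is also argued against, since the ratios were 48.2 and 30.7 with a minimum of 200 genes and 132 and 143 without a mitochondrial maximum. Unequal release of epithelial layers during the digestion, differences between animals or library preparations, and the diet itself cannot be told apart, because each diet had 1 library.

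The second pattern was the higher level of immediate early and inflammatory genes in milk-only keratinocytes, smaller without cluster 6 (-0.67 and -1.85 for hay, -0.39 and -1.93 for concentrate). Immediate early and heat shock genes also led clusters drawn mostly from a fed library. Cluster 2, with 2312 of 2428 cells from hay, had HSPA6, HSPA1A and FOSB among its leading genes with a symbol. Cluster 3, with 1157 of 1300 cells from concentrate, had HSPA6, FOSB, FOS and HSPA1A. Free RNA from the T or NK-like and macrophage or dendritic-like cells of that library is argued against. Across 26 of these genes the level in milk-only keratinocytes had a median of 197% of that in these immune cells. The highest of 12 immune markers, CD4, reached 0.503%. No cluster was named as neutrophils, so free RNA from neutrophils, whose list holds S100A12, was not tested. A handling response of all cell types in that library was examined in immune cells for immediate early genes, concentrate over milk only. After removal of keratinocyte RNA the median log2 ratio was 1.37 in T or NK-like cells (11 genes, 3 lower). It was 1.83 in macrophage or dendritic-like cells (13 genes, 2 lower), and both were above the bound set for a lower level. The removal can inflate these values, because a gene it brought below 3 counts was set to 3 counts. That limit is a higher CPM in the concentrate sums (123053 and 192676 UMIs) than in the milk-only sums (2023515 and 1671773). Before removal the medians were 0.47 and 0.90, not lower with concentrate either, which argues against such a response for these genes. Inflammatory genes and the hay library were not part of this test, so it stays open there. A response of keratinocytes alone to digestion and a diet effect stay open, as hypotheses without a test.

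The third pattern was the higher level of butyrate and ketogenesis genes in both fed libraries. More differentiated cells with milk only as the whole cause are argued against, since without that cluster the medians were 0.62 for hay and 0.46 for concentrate, above the random range. Whether the pattern rests on cluster 6, with 1021 of its 1024 cells in the milk-only library, stays open: without it the medians were 0.029 and 0.23, within the random range, while in cycling cells, which hold no cells of it, they were 0.50 and 0.36, above that range. Without cluster 6 and the differentiated cluster together, the median stayed above the random range for hay and came within it for concentrate. A diet effect stays open as a hypothesis.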

How the results depend on the processing

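Of the alternatives below, the common UMI minimum, the minimum relative to the median, these minimums with the classes kept, the absence of a mitochondrial maximum, the Scrublet score limit and the sums without clusters were chosen after seeing the data. No paired analysis was possible because each diet had 1 library, and leaving out a library was not possible for the same reason. An alternative with doublets kept was not run, since 0 cells were called doublets and it would equal the reported values. Depth limits the shares, as the lowest UMI count per barcode was 727, 2263 and 1047 with milk only, hay and concentrate.

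Across the alternatives, the ratios of shares stayed within their intervals 48 times, moved 35 times and reversed 1 time. The differentiated and cycling shares themselves stayed within their intervals 37 times and moved 47 times. The median of a main list kept its place above, below or within the random range 190 times, came within the range 34 times, left it 9 times and reversed 1 time. Apart from a reversal, the sign of the median did not enter these counts. Other lists kept their place 745 times, came within the range 54 times and left it 47 times. Named genes stayed within their intervals 793 times, moved 791 times and reversed 6 times. The ratio of differentiated shares, milk only over a fed library, was above 1 in each alternative, from 4.35 to 519 over hay and from 2.27 to 361 over concentrate. All main lists kept their side of the random range under median-of-ratios scaling and with the common UMI minimum. Unless the leaving out of a class or cluster gives it, the cause was not tested for any value below.

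Ratios of differentiated shares are given first. A minimum of 200 genes gave 48.2 over hay, and a minimum of 1000 genes 4.35 over hay and 2.27 over concentrate. With a mitochondrial maximum of 10% milk only over hay was 14.7 and concentrate over hay 0.642. Resolution 0.3 gave 4.54 over hay, 6.88 over concentrate and 0.659 for concentrate over hay, and resolution 1.2 gave 3.42 for milk only over concentrate and 10.3 for concentrate over hay. Over hay and concentrate, centred values gave 519 and 361, thinned cells 17.2 and 9.38, the common UMI minimum 5.11 and 3.24, the relative minimum 19.1 and 9.23 (14.7 and 13.6 with the classes kept), and no mitochondrial maximum 132 and 143.

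Ratios of cycling shares with a minimum of 200 genes were 2.89 for hay over milk only, 1.82 for concentrate over milk only and 1.59 for hay over concentrate. Hay over concentrate was 1.25 with 1000 genes, 1.0 with centred values, 1.03 without stage and cycle genes, and 0.97, a reversal, with the relative minimum. Hay over milk only was 1.55 with the common and 1.48 with the relative UMI minimum, or 1.55 with the relative minimum and the classes kept. Without a mitochondrial maximum hay and concentrate over milk only were 1.43 and 1.35, and without cells of high Scrublet score 1.49 and 1.24.

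Medians of lists that came within or left the random range follow. For 1000 genes S phase, concentrate against hay, was -0.010, now below the range. Thinned cells gave spinous 0.18 and cornified 0.26 for concentrate against hay, and S phase 0.42, now above, for concentrate against milk only. Without the 50 most abundant genes butyrate was -0.022 for concentrate against hay. Per-cell means gave spinous 0.20 and cornified 0.47 for concentrate against hay, and butyrate 0.32 and S phase 0.43, now above, for concentrate against milk only. At 1 CPM butyrate was 0.019, 0.22 and 0.045 for hay against milk only, concentrate against milk only and concentrate against hay, and at 50 CPM S phase was 0.29 for hay against milk only. Over all kept cells butyrate was 0.054 for concentrate against hay, and S phase 0.26, now above, for concentrate against milk only.

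With the classes weighted alike, hay against milk only had spinous -0.42, cornified -0.59, S phase 0.013 and G2 and M phase -0.65, now below. Concentrate against milk only had spinous -0.18, cornified -0.018 and G2 and M phase 0.12, and concentrate against hay spinous 0.21 and butyrate 0.0038. Reversed genes were LYPD3 at 0.062, GJB2 at 0.28 and ERO1A at 0.10 for concentrate against milk only, and S100A9 at -0.37 for concentrate against hay.

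Without cluster 6 butyrate was 0.029, 0.23 and -0.018 in the 3 comparisons in the order above, and G2 and M phase -0.75, now below, for hay and -0.080 for concentrate against milk only. Without the differentiated cluster hay against milk only had basal -0.46 and G2 and M phase -0.52, both now below, cornified -0.84 and S phase 0.015. Concentrate against milk only had cornified -0.040, and concentrate against hay spinous 0.31 and cornified 0.54. GJB2 reversed to 0.14 for concentrate against milk only. CNFN went to -1.56 for concentrate against hay, but no hay count of it was left, so this value rests on the limit of 3 counts. It is not a measured reversal. Without both clusters spinous was 0.31, cornified 0.54 and butyrate -0.011 for concentrate against hay. Concentrate against milk only had cornified -0.46, butyrate 0.25 and G2 and M phase -0.34, a reversal, and hay against milk only had S phase -0.13 and G2 and M phase -1.02, now below.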

Other observations

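All genes in this part were chosen after their values were seen, and no test was run on them.

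In keratinocytes PSMB9, a subunit that trims peptides for class I presentation, stood at 54.7, 81.1 and 11.6 CPM with milk only, hay and concentrate, PSMB8 at 78.3, 92.8 and 16.9 CPM, and B2M at 32.5, 29.7 and 5.63 CPM. In T or NK-like cells PSMB9 was at 799 CPM (761 to 839) with milk only and 1528 CPM (1317 to 1763) with concentrate, and B2M at 269 CPM (247 to 293) and 252 CPM (171 to 358). The 8 such cells with hay were not compared, because KRT15 stood at 6784 CPM in them, against 1774 CPM with milk only and 2397 CPM with concentrate, a sign of more keratinocyte RNA in them. In macrophage or dendritic-like cells PSMB9 was at 1517 CPM (1459 to 1577), 1884 CPM (1657 to 2133) and 1811 CPM (1626 to 2012) with milk only, hay and concentrate. The difference between cell types was not tested.

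IL17F, a cytokine of type 17 lymphocytes, stood at 2896 CPM (2822 to 2971) in 331 T or NK-like cells with milk only and 1040 CPM (868 to 1237) in 44 with concentrate. IL1B, an inflammatory cytokine, stood at 9982, 189 and 1490 CPM in 112, 31 and 50 macrophage or dendritic-like cells.

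DCN and POSTN, which encode matrix proteins and are also made by fibroblasts, were present in milk-only keratinocytes at 167 and 26.6 CPM, against 2.91 and 0.20 CPM with hay and 23.6 and 0.54 CPM with concentrate. The fibroblast collagen COL3A1 stood at 0.128, 0.155 and 2.25 CPM in keratinocytes and at 26921 CPM in the fibroblast-like cluster. LGALS1 was at 2847 CPM in that cluster and at 269 CPM in concentrate keratinocytes.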
